A study of Homo sapiens with 6 samples.

How the data were processed

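RIP-seq had been done on HEK293T cells in 3 SNRPD2 overexpression samples and 3 control samples. The peak lists of the overexpression samples, 1 per sample, were analysed; files of the control samples were not analysed here, and the samples were grouped by genotype per the labels. Per the submitters' processing notes, cutadapt 4.2, STAR 2.7.10b and MACS2 2.2.9.1 were used with build GRCh38. The background library, the caller's options, the treatment of duplicate reads and the strand are not given in the sources used here. The extraction text in the labels describes total RNA with ribosomal RNA depletion and does not describe the immunoprecipitation.

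The deposited score of a peak is the whole part of 10 times its −log10 p. The deposited fold was read as the scaled pileup at the summit plus 1, over the caller's background plus 1. It is therefore not a plain ratio of reads, and it depends on the scaling of each list. The deposited −log10 p-value is unadjusted and the deposited −log10 q-value is 0 for 80.6%, 83.5% and 95.3% of the peaks of replicates 1, 2 and 3. The other deposited columns give peak starts, ends and summit offsets. Folds and scores are the authors' own and were used only to describe and rank peaks within a list. The smallest −log10 p was 2.00 in each list. Peak numbers in the lists began at 829, 5159 and 1884 and ran without gaps to 30939, 166089 and 67004. The lists begin on chromosome 1, so 828, 5158 and 1883 peaks numbered before it are not in the lists analysed, and their positions are unknown. Counts, ranks and absences hold for the listed peaks only.

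Reads at a summit were recovered from the fold and −log10 p by finding the height of 1 read in the caller's scaled pileup (0.599, 1 and 0.254 in replicates 1, 2 and 3) that gave a whole number of reads with the deposited p within 0.002 on the −log10 scale. This solved all but 1 of the peaks, in replicate 3. Among distinct pairs of fold and p, 4 wrong heights solved at most 4.36%, 4.10% and 8.83%. Sequencing depth is otherwise unknown, since peak lists give no library totals. The reads behind each peak set its precision, and duplicates cannot be told from independent molecules. The share of loci with a summit carries the spread of 3 replicates.

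Genes were taken from a RefSeq table of the same build, with 59665 symbols on the nuclear chromosomes and only whole gene spans. Exons, introns and sequence were not used here, so the planned classes of exons and introns, the distance to splice sites and the density of pseudouridine motifs were left out. With them went their alternatives, the list alternative limited to exons and the matching on exonic length. Gene classes of summits and the small RNA families were added after the data were seen. Without strand, a peak in overlapping genes cannot be assigned to one of them, and the gene classes settle this by a fixed order only.

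Overlap needed 1 bp. Each peak was moved 100 times within its own merged gene locus (36481 loci), or outside genes on its chromosome. Shared segments were covered by all 3 lists over at least 20 bp. Gene classes were compared with 1000 sets of random positions between the first and last gene of each chromosome. Where genes overlap, a position took 1 class by a fixed order. Small RNA genes and pseudogenes came before protein-coding genes, and protein-coding genes before long noncoding RNA genes. Lists of genes (20 lists, 602 genes) were fixed before the data were examined. Of these genes, 2 had no match in the table. The 14 protein-coding lists were compared with protein-coding genes that had a peak in any list, by Fisher's exact test. The remaining lists are 4 groups of small RNA genes, long noncoding RNAs and mitochondrially encoded genes. Benjamini-Hochberg adjustment was applied within each family of tests, at 0.05. For the alternatives, the small RNA family tests were adjusted over the comparisons and replicates of each setting.

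Named genes were set before the data were examined: SNRPD2, PUS7, small RNAs with peaks in all 3 lists, the top 10 protein-coding and top 5 other genes by mean percentile of the fold at shared segments, and the top 3 of each list. Some genes that this rule names are not reported here. The value given for a gene is that of the peak with the highest −log10 p whose summit lies in it. Other small RNAs, RNU4-1 among them, and genes listed for one replicate were named after their values were seen.

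Alternatives set beforehand were a −log10 q of at least 3, lists of equal length, reciprocal overlap of 50%, placement in any gene body, segments of at least 100 bp or in 2 of 3 replicates, coverage of 50% of a small RNA gene, other list backgrounds (all protein-coding genes, or 10000 random lists matched on gene length), and leaving out each replicate. Added after the data were seen were peaks of at most 1000 bp, 50 nt on each side of the summit, and at least 10 reads. The steps were tested on simulated data. Known read numbers were recovered for 99.3%, 99.0% and 98.5% of simulated peaks at 3 heights of a read. A simulated list that shared 29.7% of replicate 1 peaks gave an overlap of 31.2% against 2.52% by placement. In 100 simulated sets of 14 gene lists, 88.0% of the lists made to differ were called, and 1.10% of the others. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.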

Results

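RNA immunoprecipitation followed by sequencing (RIP-seq) recovers the RNAs bound by a protein. The series used it for SmD2, encoded by SNRPD2, a subunit of the ring of Sm proteins around most spliceosomal small nuclear RNAs (snRNAs). The cells were HEK293T, an established human embryonic kidney line. Its stated purpose was to examine how SmD2 interacts with pseudouridine, a modified RNA base that PUS7 installs, and with mRNA splicing. The labels gave 3 RIP samples from cells overexpressing SNRPD2 and 3 control RIP samples. A peak list was analysed for each overexpression sample, and the control samples were not analysed here, so no test between the groups was made. The labels do not say whether the replicates came from separate cultures, and the spread between them may be technical.

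The lists held 30111, 160931 and 65097 peaks on the nuclear chromosomes in replicates 1, 2 and 3. Median peak width was 77 bp, 40 bp and 12210 bp. Replicate 3 stood apart, since 49284 of its peaks (75.7%) were wider than 1000 bp, against 2 in replicate 1 and 0 in replicate 2. Its peaks covered 1975 Mb, or 64.0% of the length between the first and last annotated gene of each chromosome, against 2.72 Mb and 9.75 Mb in replicates 1 and 2. The peaks were called at an unadjusted p of 0.01, and 1447, 5820 and 1208 of them had a deposited q-value under 0.05. The deposited fold and −log10 p of a peak together returned the number of reads at its summit. A single read lay at the summit of 0, 114912 (71.4%) and 35777 (55.0%) peaks, and 5627, 8403 and 5449 peaks had at least 10. The highest number of reads was 78, 80 and 78, which in each list equalled 2 times the smallest peak width of 39, 40 and 39 bp. A ceiling on reads at this number, which would limit folds at abundant RNAs, was inferred from this match and not tested.

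**Figure D1:**
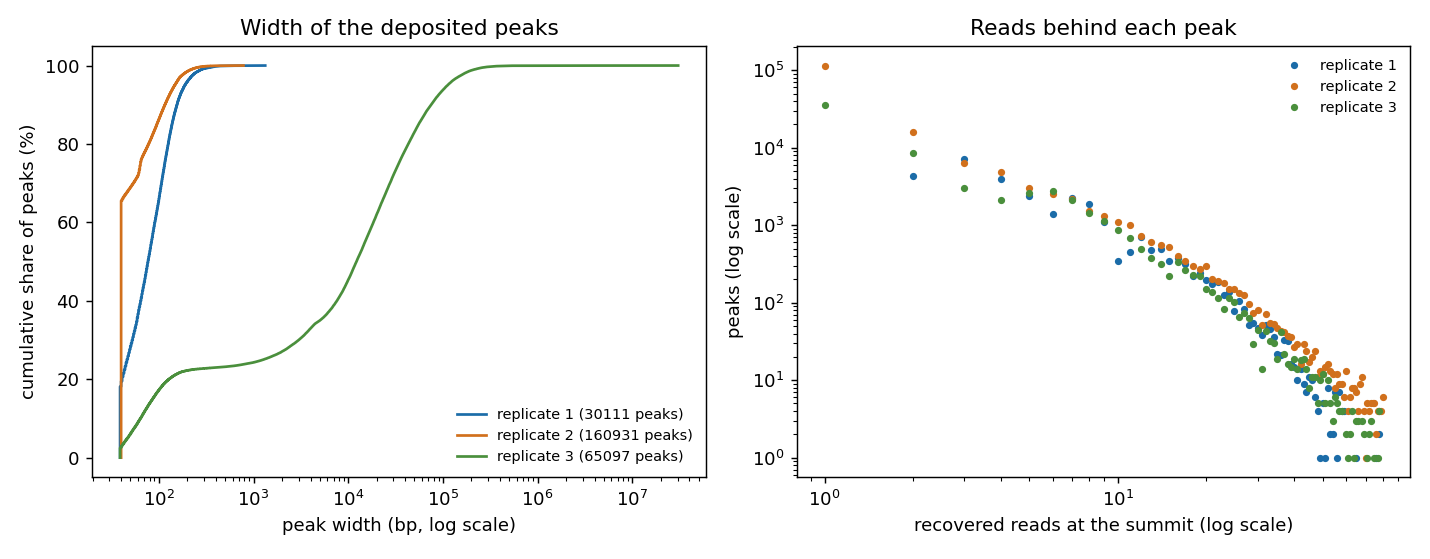
Left, cumulative share of peaks (%) by width (bp, log scale) in each of the 3 lists; right, number of peaks (log scale) by recovered reads at the summit (log scale). Replicate 3 holds 49284 peaks wider than 1000 bp, and no list goes beyond 80 reads.

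Replicates 1 and 2 placed peaks at the same positions far more often than random placement did. Of the peaks of replicate 1, 35.5% overlapped a peak of replicate 2 by at least 1 bp, against 3.60% ± 0.107 (SD over 100 placements within the same gene locus). Of the peaks of replicate 2, the longer list, 6.69% overlapped replicate 1, against 0.682% ± 0.0212. Placement took no account of exons or of RNA abundance, so overlap above it does not by itself show shared binding sites. Overlap with replicate 3 depended on the direction: 30.3% of replicate 1 peaks and 50.5% of replicate 2 peaks overlapped one of its peaks, below the 36.3% and 53.9% of random placement. Of its own peaks, 13.2% overlapped replicate 1 and 58.5% replicate 2, above the 12.02% and 44.8% of placement. Without the peaks wider than 1000 bp the overlaps of replicates 1 and 2 with replicate 3 were 14.1% against 1.13%, and 3.50% against 0.407%, above placement. Over all 6 ordered pairs the mean overlap was 32.4% against 25.2% (one-sided randomization test, exact Monte Carlo p = 0.0099, the smallest that 100 placements can give). Without replicate 2 the mean overlap fell below placement, at 21.7% against 24.2%. Peaks of all 3 lists covered 3361 segments of at least 20 bp, with a median length of 50 bp, and 93.3% of segment midpoints lay in an annotated gene. Replicates 1 and 2 alone gave 9790 segments, and the 3361 were 34.3% of that number. By a like but not equal measure, 36.3% of randomly placed replicate 1 peaks met a peak of replicate 3. Coverage by replicate 3 therefore does not by itself show that a segment is reproduced. Without the wide peaks all 3 lists gave 1796.

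**Figure D2:**
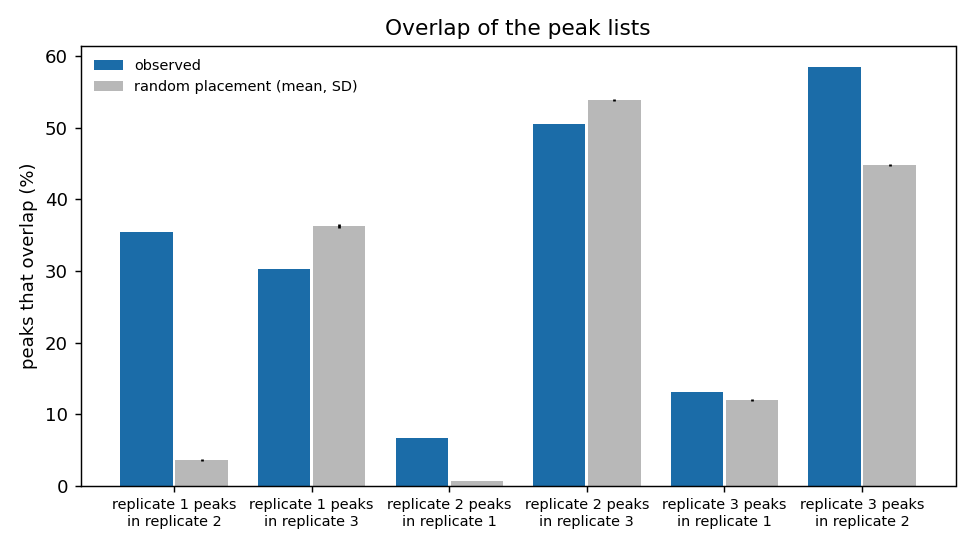
Share of peaks (%) of one replicate that overlap a peak of another by at least 1 bp (blue), beside the mean of 100 random placements (grey, error bars SD). Peaks of replicates 1 and 2 overlap those of replicate 3 less often than placed peaks do, at 30.3% and 50.5% against 36.3% and 53.9%.

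Peak summits lay mainly in protein-coding genes and were most concentrated, for the length they occupy, in tRNA, snRNA, snoRNA and scaRNA genes. Where genes overlap, a summit was counted for small RNA genes and pseudogenes first, then protein-coding genes, then long noncoding RNA genes. Protein-coding genes held 76.7% ± 11.6 of the summits (SD, n = 3 replicates), 1.80-fold ± 0.254 the number given by random positions on the same chromosomes. Transfer RNA genes, which encode the adaptors of translation, held 112-fold ± 74.3 the random number. Genes of snRNAs held 44.8-fold ± 18.6, and those of snoRNAs and scaRNAs, which guide modification of other RNAs, held 26.6-fold ± 16.6 (17.4-fold without replicate 3). Pseudogene copies of snRNAs held 10.9-fold ± 3.59, and other pseudogenes 2.18-fold ± 0.136. Genes of long noncoding RNAs held 0.453-fold ± 0.268, and positions outside genes 0.311-fold ± 0.195. With at least 10 reads long noncoding RNAs and positions outside genes fell to 0.0501-fold and 0.0365-fold. At that setting tRNA genes rose to 555-fold, snRNA genes to 253-fold, and snoRNA and scaRNA genes to 234-fold. With all peaks, each of these classes departed from random positions in every replicate (randomization test with 1000 placements and an exact Monte Carlo p, largest Benjamini-Hochberg adjusted p = 0.00107). Random positions take no account of how abundant each RNA is, so a departure from them does not show binding by SmD2. Other small RNA genes held 1.74-fold ± 0.476 and did not depart from random positions in replicate 3 (exact Monte Carlo, adjusted p = 0.395), though they did in every replicate used with lists of equal length, peaks of at most 1000 bp, at least 10 reads, or without replicate 3. The strongest peaks differed between the lists by this order of classes. Of the 100 peaks with the highest −log10 p, protein-coding genes took 56 and 61 in replicates 1 and 2. They took 7 in replicate 3, where 48 went to other pseudogenes and 29 to snoRNA or scaRNA genes. Summits that also lie in a protein-coding gene, as those at RNU4ATAC in CLASP1 and SNORD89 in RNF149, are not among the 7. Near-identical copies share reads, so values at a single tRNA, snRNA or pseudogene locus are uncertain.

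The fixed groups of small RNAs asked whether the snRNAs that carry the Sm ring had peaks where those without it did not. Of 27 genes of Sm-class snRNAs (U1, U2, U4, U5, U11, U12 and U4atac), 12, 20 and 13 had a peak in replicates 1, 2 and 3, and 5 had one in all 3 replicates. All 5 were forms of U1, the snRNA that recognises the 5′ splice site: RNVU1-6, RNVU1-14, RNVU1-15, RNVU1-18 and RNU1-27P. Forms of U1 also made up most of the 27 genes. RNU1-27P is annotated as a pseudogene, and its peak in replicate 1, 339 bp wide, had its summit outside it. The count was 10 without replicate 1, where RNVU1-7, RNU2-2, RNU4-1, RNU5E-1 and RNU4ATAC joined, 6 without replicate 2, 9 without replicate 3, and 1 at a −log10 q of at least 3. RNVU1-14, on chromosome 1 from 145281116 to 145281279 (GRCh38), had folds of 4.85, 6.68 and 8.11 with 55, 60 and 60 reads. None of 6 U6-class genes and not the U7 gene RNU7-1 had a peak in all 3 replicates (5 of 27 against 0 of 7, two-sided Fisher's exact test, p = 0.559). With 5 such genes and 7 in the comparison group this test could not have passed in that direction, so it does not decide whether the groups differ. Without replicate 1 the U6-class genes RNU6-7 and RNU6ATAC had a peak in each remaining list, and without replicate 2 RNU6-1 did. Of 14 other small noncoding RNAs, among them RN7SK, RN7SL1, RMRP and RPPH1, none had a peak in all 3 replicates, and RNY3 had one in replicates 2 and 3. Several snRNAs were close to the highest number of reads, as RNU4-1 was with 78 reads and a fold of 1.46 in replicate 2, so a missing peak at an abundant RNA does not show that it was unbound.

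Counting each family's genes together with its pseudogene copies, a comparison added after the data were seen, gave U1 a higher share with a summit than U6, 7SL, 7SK and Y RNAs. U1 was not tested against the other families. A summit lay in 27.8% ± 9.08 of the 144 U1 loci (SD, n = 3 replicates). The shares were 17.4%, 31.9% and 34.0% by replicate, against 2.22%, 3.50% and 2.31% of 2342 loci of U6, 7SL, 7SK and Y RNAs (Fisher's exact test, adjusted p = 4.18e-13, 2.69e-26 and 5.47e-35). These tests, and those of the families below, count loci within 1 list. Copies of a family can share reads, so loci are not independent and the p-values do not measure spread between replicates. The other Sm-class families, U2, U4, U5, U11, U12 and U4atac, had a summit in 2.703%, 12.2% and 8.56% of 222 loci. U6 and U6atac had one in 0.453%, 2.19% and 0.906% of 1324 loci (Fisher's exact test, adjusted p = 0.00583, 1.70e-09 and 3.07e-09). Not every replicate passed at a −log10 q of at least 3 or with at least 10 reads (Fisher's exact test, largest adjusted p = 0.229 and 0.0628). U7, whose ring holds other proteins in the place of SmD2, had a summit in 0 of 169 loci in each replicate, the lowest share possible. Against U6 and U6atac (adjusted p = 1, 0.0934 and 0.490, Fisher's exact test) these counts were too few for a lower share to pass, so whether U7 differs stays open. The families were not uniform: U6atac had a summit in 10.3% ± 7.65 of 42 loci, close to the 11.3% ± 6.45 of the 71 U2 loci (SD, n = 3). 7SK had one in 5.90% ± 0.786 of 294, close to the 5.49% ± 3.96 of the 91 U4 loci. With at least 10 reads 7SK had 1.02% ± 0.340 against 1.83% ± 0.634 for U4. At that setting U6atac had 4.76% in each replicate against 2.35% ± 0.813 for U2.

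**Figure D3:**
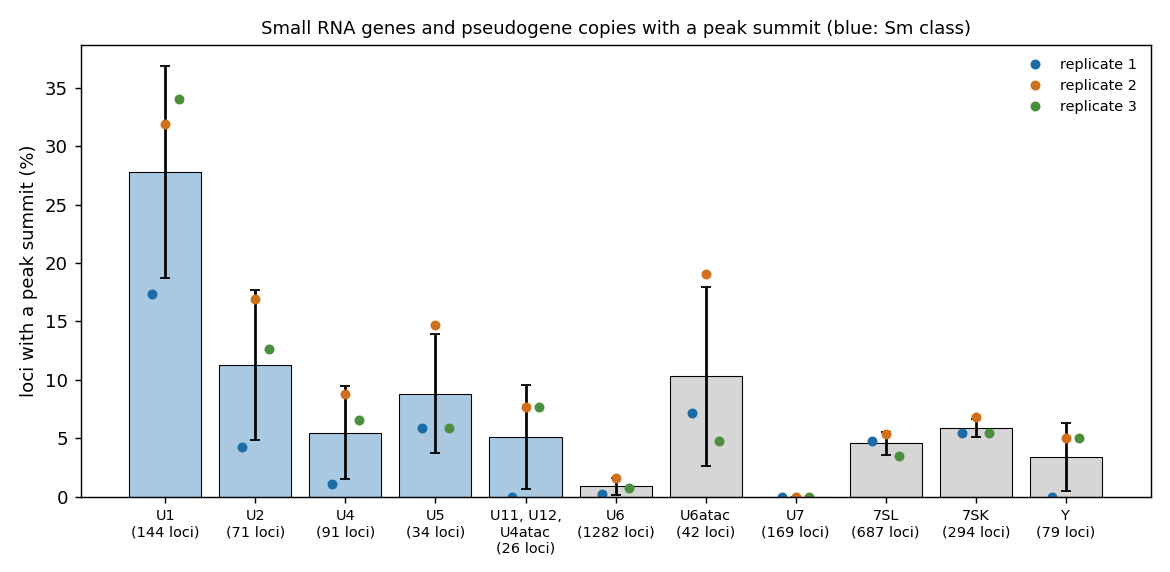
Share of the genes and pseudogene copies of each small RNA family that hold a peak summit (%). Bars are means of 3 replicates, error bars SD, points single replicates, and blue marks families of the Sm class; U1 reaches 27.8% and U7 stays at 0.

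SNRPD2 itself, on chromosome 19 from 45687454 to 45692316, had a peak in each list with 78, 80 and 78 reads, the highest number in each list, and folds of 2.17, 2.79 and 3.46. The highest-ranked gene was SNRPD2P1, a copy annotated as a pseudogene of SNRPD2, on chromosome 10 from 89978662 to 89979168. Its folds were 23.3, 27.99 and 7.28, with 38, 28 and 25 reads over a background of 0.0373, 0.0361 and 0.0316 reads. This peak was the strongest of replicates 1 and 2. A read counted for 0.599, 1 and 0.254 in the scaled pileup, so these folds are not compared between replicates. PUS7, the pseudouridine synthase named in the study's design, had folds of 3.15, 5.43 and 4.87 with 4, 6 and 16 reads, but no segment covered by all 3 replicates. Among protein-coding genes SNRNP70, which encodes the U1-70K protein of the U1 particle, ranked first, with 10 shared segments. Its strongest peaks had folds of 6.06, 5.26 and 9.07 but did not lie at 1 site. That of replicate 1 lay at the low-coordinate end of the gene span, and those of replicates 2 and 3 at the other end. The rank was taken at shared segments, and these folds as a set are not the values behind it. SF3A3, a subunit of the U2-associated SF3A complex, had folds of 7.99, 8.20 and 5.62, and NUP133, a nuclear pore scaffold protein, 7.09, 13.7 and 6.50. GET3, which delivers tail-anchored proteins to the endoplasmic reticulum, had folds of 8.08, 6.51 and 6.55, and TTL, the tubulin tyrosine ligase, 9.55, 9.46 and 4.64. USP9X, a deubiquitinase, held 30 shared segments, and NTMT1, an N-terminal methyltransferase, held 1. FUNDC2 held 5. WDR74 and USP32 also ranked among the top 10, but their strongest peaks in replicate 3 are ambiguous, since they lie at RNU2-2 and at SCARNA20 inside the gene spans. The other top genes that do not code for protein were SEC61G-DT, LOC107984778, PRELID1P6 and LOC112268274. PRELID1P6 had the same mean percentile as WDPCP, and LOC112268274 the same as the snRNA gene LOC124904613. The ranks of both may come from overlapping genes and are ambiguous.

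**Figure D4:**
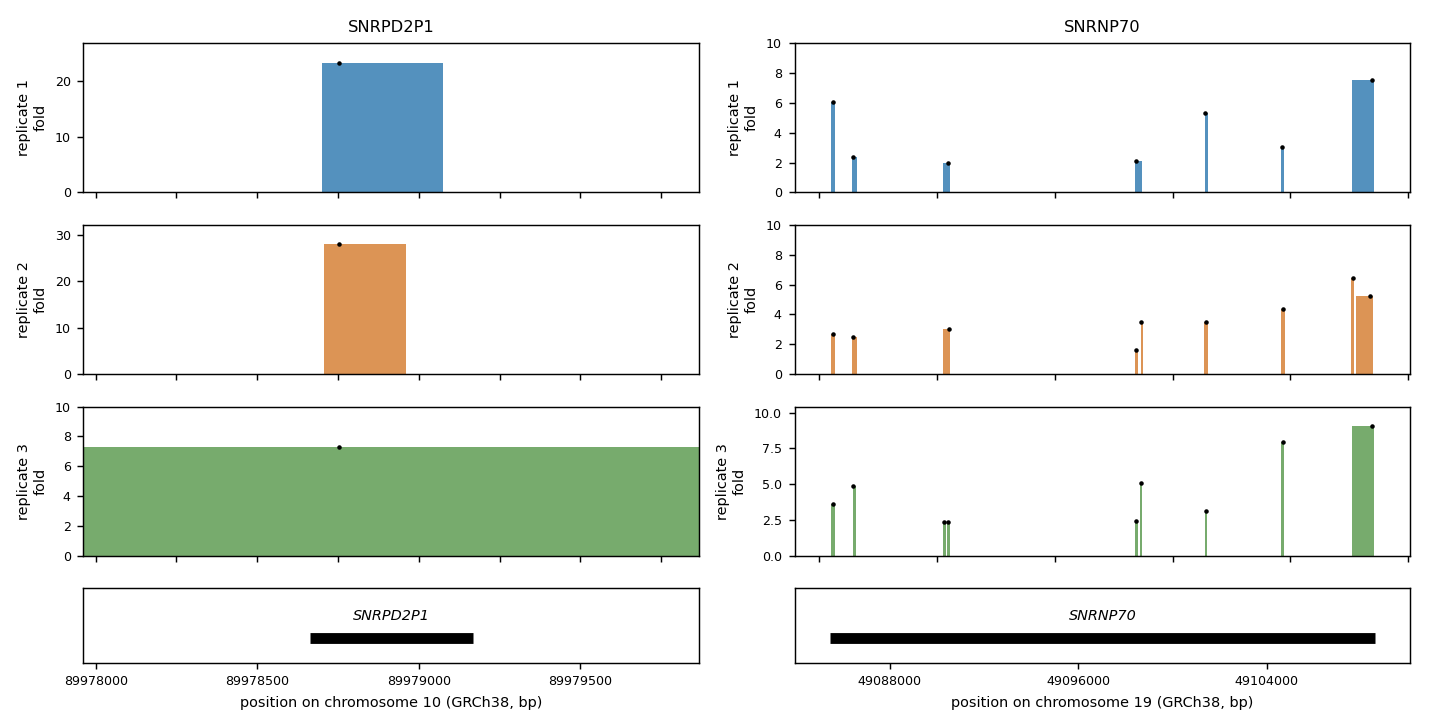
Peaks at SNRPD2P1 (left) and SNRNP70 (right) along GRCh38 (position in bp), 1 row per replicate; boxes span each peak, their height is the deposited fold, and dots mark summits. The summits at SNRPD2P1 fall together, at folds of 23.3, 27.99 and 7.28, while the replicate 3 peak runs beyond the region drawn.

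Of 14 fixed lists of protein-coding genes, 4 held a shared segment more often than the other protein-coding genes with a peak. Of all 18555 such genes, 11.7% had a segment. In the DNA replication list 13 of 41 genes (31.7%) had a segment (Fisher's exact test, adjusted p = 0.00747), among them CDC45, a component of the replicative helicase, POLA2, a subunit of DNA polymerase alpha, and GINS3. In the DNA damage response list 12 of 42 (28.6%) did (Fisher's exact test, adjusted p = 0.0166), among them XRCC5, which joins broken ends, and the repair genes ERCC6 and ERCC2. Some of these examples are weak. The strongest GINS3 peak had a −log10 q of 0 in each list, and that of ERCC6 in replicate 3 was 21699 bp wide with 6 reads. Proteins specific to single snRNPs and to the SF3 complexes had 10 of 34 (29.4%, Fisher's exact test, adjusted p = 0.0172), among them SNRNP70, SF3A3 and DHX8. Factors of snRNP assembly had 6 of 15 (40%, Fisher's exact test, adjusted p = 0.0172). Among them were COIL, and GEMIN5 and GEMIN4 of the complex that loads the Sm ring onto snRNA. The tests were two-sided, with Benjamini-Hochberg adjustment over the lists. With only peaks of at least 10 reads, or of a −log10 q of at least 3, 0 lists passed, although snRNP assembly differed by 31.6 percentage points with at least 10 reads. Of the 4 only the DNA damage response list passed without replicate 1 and only the DNA replication list without replicate 2, where the differences of the other 3 stayed at 15.2 to 26.1 points. Against random lists matched on gene length the DNA damage response list did not pass (12.7 percentage points, randomization test with 10000 lists and an exact Monte Carlo p, adjusted p = 0.136), and transcript levels were not used here, so the lists were not matched on expression.

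The other 10 lists did not pass this test, but some passed under an alternative. Without replicate 1, the difference from other genes was -46.2 percentage points for ribosomal proteins and -45.9 for histones (Fisher's exact test, adjusted p = 3.19e-13 and 1.47e-05). With all 3 replicates these were -7.14 and -11.7, and 0.261 and -2.08 against random lists matched on gene length. Against all protein-coding genes the histones passed, at -10.8 (Fisher's exact test, adjusted p = 0.0232). Without replicate 3, cancer driver genes were 29.2 points above, and with peaks of at most 1000 bp 13.3 points above (Fisher's exact test, adjusted p = 0.000234 and 0.0124). Tissue-restricted genes passed lower without replicate 2 (-21.0 points) and without replicate 3 (-23.0; Fisher's exact test, adjusted p = 0.0338 and 0.0391). Oxidative phosphorylation genes passed in opposite directions without replicate 1 (-22.8) and without replicate 3 (17.4; Fisher's exact test, adjusted p = 0.0165 and 0.0481). SR proteins had 4 of 16 genes with a segment (SRSF9, TRA2A and TRA2B among them), and pseudouridine synthases and box H/ACA proteins had 4 of 15, among them PUS10, TRUB2 and RPUSD3. Cancer driver genes had 10 of 48, among them NF2, SMARCA4 and AKT1, and nuclear genes of oxidative phosphorylation had 6 of 39, among them NDUFV1 and UQCRC1. Genes of mitosis had 5 of 36, among them PLK1, TPX2 and KIF4A. Among RNA-binding proteins, hnRNP proteins had 3 of 25 (HNRNPD, HNRNPAB and HNRNPUL1), and Sm and LSm proteins had 2 of 16 (SNRPD2 and LSM1). Cytosolic ribosomal proteins had 3 of 66, among them RPL23 and RPL34, tissue-restricted genes had 2 of 38 (TNNI3 and CD8A), and replication-dependent histones had 0 of 26. The RPL23 segment is ambiguous, since the snoRNA gene SNORA21B had the same mean percentile and may hold it. In replicate 3 the strongest peaks at SMARCA4, KIF4A and CD8A were wide, at 2279, 6759 and 28479 bp, with 8, 6 and 2 reads. Of 24 long noncoding RNAs, 0 held a shared segment, including MALAT1 and NEAT1.

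**Figure D5:**
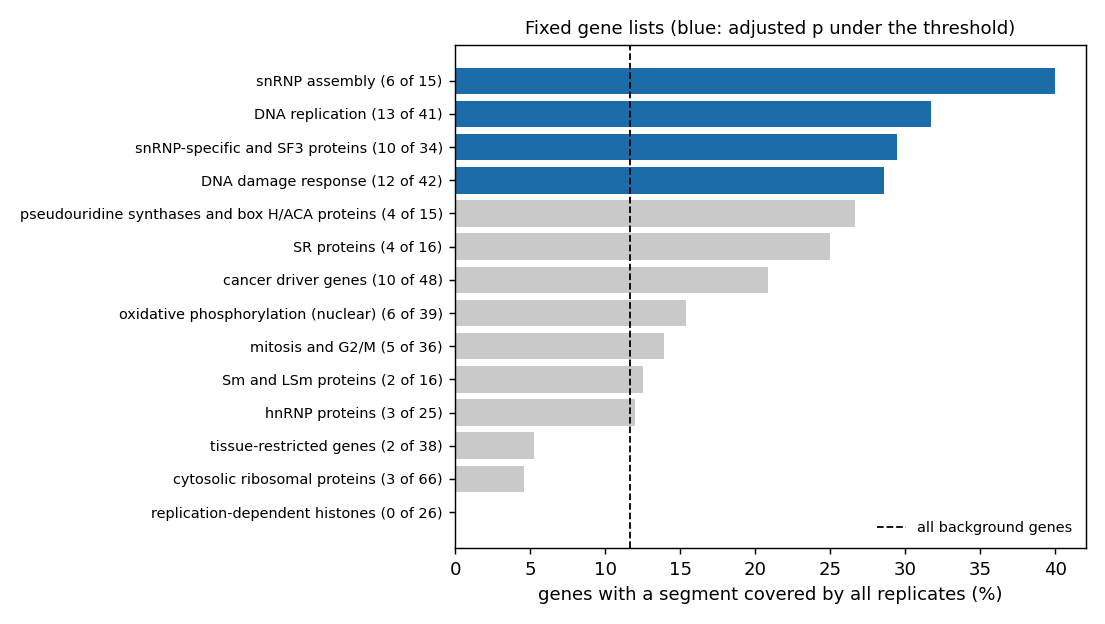
Share of each fixed list's genes with a segment covered by peaks of all 3 replicates (%), with counts beside the names; the dashed line is the 11.7% of all background genes. The 4 blue lists passed the test.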

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

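The tests chosen only after the result was seen are those of the low background, of the reads in wide peaks, of wide peaks beyond a locus, and all those on the copy of SNRPD2; the comparison of small RNA families was itself added after the data were seen.

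Peaks on the mitochondrial chromosome, which the comparisons did not use, appeared in replicate 3, where 24 were listed against 0 in replicates 1 and 2. Their summits lay in 9 of the 15 mitochondrially encoded genes of the fixed list, COX1 and CYTB among them, with a highest fold of 9.35.

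The wide peaks of replicate 3 may be stretches of low background. Of these peaks, 99.8% had the lowest background of the list at the summit, where the chance of at least 1 read is 0.00799. By the form of p that recovered the reads, positions at that background pass a p of 0.01 even without reads. In replicates 1 and 2 the lowest background gives 0.0221 and 0.0329, above that p. At the summit, 94.1% of the wide peaks had 1 to 3 reads. At a height of 0.254 per read, 1 to 3 reads give the same p there as no reads. That share and the low background are therefore not separate lines of evidence. Reads spanning introns of 1 transcript predicted wide peaks inside single loci, and 57.7% lay inside one against at most 40.7% by placement, but the remaining 42.3% reached beyond 1 locus, which argues against it as the whole cause. No biological explanation was tested, since no group with another genotype was analysed.

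The peaks in U1 genes and copies were weighed against reads of any abundant small RNA spread over its copies, which predicted like shares for U6, 7SL, 7SK and Y loci. The U1 share was at least 7.82 times theirs in each replicate, so the shares were not alike. Most of the pooled loci were U6 (1282 of 2342), and the highest single family was 7SK, at 5.44%, 6.80% and 5.44% by replicate. How alike the copies of each family are was not examined, so the test does not exclude spread of reads over copies. A candidate explanation is that Sm-class RNAs as a class carry peaks, and the other Sm-class families had a summit at least 5.55 times as often as U6 and U6atac. Over all peaks, shares close to each other for 7SK (5.90%) and U4 (5.49%), and for U6atac (10.3%) and U2 (11.3%), go against a clean division by class. With at least 10 reads 7SK (1.02%) was below U4 (1.83%), while U6atac (4.76%) was above U2 (2.35%). Whether the control samples show the same stays open, so enrichment by SmD2 remains a hypothesis.

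The peak in the copy of SNRPD2 had a far higher fold than SNRPD2 itself. The reads at SNRPD2 reached 100% of an inferred ceiling in each list, which may hold down its fold. Comparisons with SNRPD2 are therefore void. The fold at the copy was at least 2.10 times that at SNRPD2. The share of reads at the copy was at least 199.7 times the share in the background, but neither decides. The background at the copy was also at or near the lowest of each list, so the 199.7 depends on that floor. Whether SNRPD2 mRNA is as abundant in the background, whether introduced or endogenous SNRPD2 reads were placed on the copy, and whether the copy's own transcript was bound cannot be told apart, because reads and sequence were not used here.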

How the results depend on the processing

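The alternatives with peaks of at most 1000 bp, 50 nt around the summit and at least 10 reads were chosen after seeing the data, as were the gene classes and small RNA families. No paired analysis was possible because the control samples, which share replicate numbers with the overexpression samples, have no files analysed here. Shared segments, 3361 as reported, numbered 18 at a −log10 q of at least 3, 1849 with lists of equal length, 1796 with peaks of at most 1000 bp, 1847 with 50 nt around the summit, 942 with at least 10 reads, 428 at 100 bp or longer, 92168 in at least 2 of 3 replicates, and 8875 to 80655 when a replicate was left out. The 4 gene lists, all higher than other genes, became 0 at that q, 1 with equal lists (snRNP-specific and SF3 proteins), 2 around the summit, 0 with at least 10 reads, 3 with length-matched lists, 5 with peaks of at most 1000 bp (cancer driver genes added), 5 against all protein-coding genes (histones added, lower), and 2 to 7 when a replicate was left out: 1 higher and 3 lower without replicate 1, 1 higher and 1 lower without replicate 2, 5 higher and 2 lower without replicate 3. DNA replication fell to 0.688 percentage points with equal lists (adjusted p = 1, Fisher's exact test), and snRNP-specific and SF3 proteins did not pass without replicate 3 (adjusted p = 0.0592, Fisher's exact test). At that q the difference from other genes turned to -0.611 percentage points for snRNP assembly, -0.613 for DNA replication and -0.611 for DNA damage response, where few segments were left; that of oxidative phosphorylation genes ran from -22.8 without replicate 1 to 17.4 without replicate 3. Mean overlap between replicates stayed above placement except without replicate 2 (21.7%; 21.1% to 54.5% when a replicate was left out). Overlap of replicate 1 and of replicate 2 peaks with replicate 3 turned from below to above placement at that q (8.31% and 4.199%), with equal lists (27.0% and 26.7%), peaks of at most 1000 bp (14.1% and 3.50%), around the summit (19.7% and 7.75%), with at least 10 reads (29.4% and 27.5%) and at 50% reciprocal overlap (7.61% and 1.71%). That of replicate 3 peaks with replicate 1 (13.2%) fell below placement in any gene body. The U2, U4, U5, U11, U12 and U4atac share was 1.502% at that q and 2.703% with at least 10 reads, and no longer passed in every replicate (largest adjusted p = 0.229 and 0.0628, Fisher's exact test). With at least 10 reads only replicate 1 lost the call, and the ratios to U6 and U6atac were 5.96, 23.9 and 13.9, against 5.96, 5.55 and 9.44 with all peaks. The U1 share kept its side of the threshold under each alternative run, at 8.56% to 33.0%. Protein-coding genes held 60.7% of summits at that q, not above random positions in every replicate. With at least 10 reads the folds over random positions were 555 for tRNA, 253 for snRNA, 234 for snoRNA and scaRNA and 8.31 for other small RNA genes, 0.0501 for long noncoding RNAs and 0.0365 outside genes. The cause of these changes was not tested.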

Other observations

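Small RNA loci were among the strongest peaks of each list. In replicate 3, RNVU1-31 had the highest fold, 20.6, and the snoRNA SNORD13, which acts in ribosomal RNA processing, had 17.6 with 71 reads. RNU4ATAC, of the minor spliceosome, had a fold of 17.9 there and 2.56 in replicate 2, and RNU5E-1 had 16.1 and 3.30. Neither had a peak in replicate 1. The reads at their summits were similar in replicates 3 and 2, at 72 and 71 for RNU4ATAC and 62 and 56 for RNU5E-1. The backgrounds were not, at 0.307 and 27.1 reads and at 0.154 and 16.3 reads. The higher folds in replicate 3 therefore do not show that more of these RNAs was recovered. SNORD89 lay under a peak with a fold of 15.99. These loci were chosen after their values were seen.

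After SNRPD2P1, the strongest peaks of replicates 1 and 2 lay in several classes of genes. The lncRNA gene LINC01836 and the pseudogene LDHBP2 followed SNRPD2P1 in replicate 1, with folds of 11.9 and 12.05, and then RNVU1-6 with 10.999. In replicate 2, RNVU1-14 came next with 6.68, and CECR2, which encodes a bromodomain protein, with 15.3. The Y RNA gene RNY3 had 11.9 there with 20 reads, 5.07 in replicate 3 with 19 reads, and no peak in replicate 1. SNRPD2P2, another copy of SNRPD2, had no summit in replicate 1 or 3 and a fold of 2.90 from 2 reads in replicate 2.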
